A study of Coturnix japonica with 29 samples.

How the data were processed

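RNA sequencing libraries from the red cell portion of blood of adult female Japanese quail were analysed as 1 table of gene counts with 29 library columns. Per the labels, blood was lysed in Qiazol, RNA was taken from the aqueous layer after chloroform and purified with a Zymo column kit that included DNase treatment, and libraries were made with the NEBNext Ultra RNA kit. The authors deposited raw read counts per Ensembl gene identifier, as whole numbers with a different total in each library. The submitters' processing notes name CASAVA 1.8.2, HISAT2 and DESeq2, without saying which step each served. The read counter, genome build, annotation release and strand setting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies could therefore not be told apart, and single identifiers carry that uncertainty. The LPS dose and the interval between injection and meeting the male are likewise not given in the sources used here.

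Libraries were placed in groups by the treatment labels, and each column was tied to its sample by the sample title. Replicates were numbered within a group in accession order, so the numbers name libraries and pair none. The labels describe each library as a separate blood sample. Over the 406 pairs of libraries, the smallest chi-square per degree of freedom between counts was 29.2 and the highest correlation of log2 CPM was 0.962, so no library was a repeat of another. No sequencing batch or date was used.

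Library totals ran from 8898747 to 14366101 reads. No read was counted in any library for 4537 genes, and filterByExpr kept 9918 of 21561 genes, which held 99.9% of the reads. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, all 3 groups in 1 fit and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.436. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The 3 comparisons were F_LPS against M_SAL, M_LPS against M_SAL, and F_LPS against M_LPS. Log2 CPM used a prior count of 2. Differences of a single value per library were tested by two-sided permutation, exact over every regrouping where a group held fewer than 10 libraries and with 100000 resamples otherwise. Principal components were computed on log2 CPM of the tested genes. Genes detected were also counted after thinning every library to the 8898747 reads of the smallest.

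The reference table holds 20956 quail genes, of which 0 carry an Ensembl identifier, so 0 of the 21561 identifiers were matched to a symbol. The gene lists and cell type markers fixed before the data were examined were therefore not tested, nor were the 7 genes that were to be reported whatever their result. The rule for naming genes, also fixed before the data were examined, took the largest absolute log2 fold changes among genes with adjusted p below 0.05 and a mean of at least 5 CPM in the higher group. It asked for a symbol, and in the absence of symbols its first 2 higher and first 2 lower identifiers in F_LPS against M_SAL are given. In place of lists, modules were defined from the data by average linkage on 1 minus Pearson's r over the 500 most variable genes, cut at a height of 0.5 and kept from 20 genes up. The modules, and the alternatives that leave out M_SAL replicates 1 and 3 or M_SAL replicate 6 with M_LPS replicates 6 and 7, were chosen after seeing the data.

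The covariance of fold changes against the shared M_SAL libraries was set beside 100 simulated draws of unchanged groups, random splits of the M_SAL libraries into 4 and 5, and 100 regroupings of M_SAL and M_LPS. The overlap of calls between the 2 comparisons that share the F_LPS libraries was also counted over 50 random splits of these libraries into 5 and 5. Over 50 random splits, genes were also chosen in 5 F_LPS and 5 M_SAL libraries, and their F_LPS values and M_LPS intervals were taken from the other libraries. The position of each library between the M_LPS and F_LPS means was also taken on genes chosen without it, leaving out every pair of F_LPS libraries and every M_LPS library in turn. These 3 steps were chosen after seeing the data, and splits with fewer than 5 chosen genes were left out of the range given. Alternatives changed 1 choice at a time: RLE (DESeq2-style size factors) or upper-quartile scaling, leaving out the 10 most abundant genes, no filter, a filter of 5 CPM in 9 libraries, DESeq2 1.42.0, voom with quality weights from limma 3.58.1, a fit of the compared groups alone, 1 surrogate variable from sva 3.50.0, and each library left out in turn. The test of each gene, the covariance, the modules, the held-out intervals and the held-out positions were tested on simulated data, and the other steps were not. In F_LPS against M_SAL, with 200 genes changed in each of 5 simulated tables, the test recovered 28.4% of genes changed 1.5-fold, 60.2% of those changed 2-fold and 89.3% of those changed 4-fold, with 3.65% false calls. For F_LPS against M_LPS the recoveries were 31.3%, 62.3% and 91.0%, with 4.75% false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.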

Results

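Gene expression was measured by RNA sequencing in the red cell portion of blood from adult female Japanese quail (Coturnix japonica), whose circulating red cells keep their nucleus. The females had been injected with saline or with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that triggers an innate immune response. Each female then spent 3 h with a male before blood was taken from the brachial vein. The 29 libraries fell into 3 groups. F_LPS held 10 libraries from LPS-injected females kept with saline-injected males, M_LPS held 10 libraries from saline-injected females kept with LPS-injected males, and M_SAL held 9 libraries from saline-injected females kept with saline-injected males. The library totals ranged from 8898747 to 14366101 reads, with a mean of 11470747 ± 1825103 (SD, n = 10) in F_LPS, 10454496 ± 1130980 (SD, n = 10) in M_LPS and 10782861 ± 842609 (SD, n = 9) in M_SAL. No pair of groups differed in total by a permutation test (adjusted p between 0.328 and 0.587, 18 tests over 6 library measures). Of 21561 genes in the table, 9918 were tested, and these held 99.9% of the reads. Gene identifiers are Ensembl quail genes that the sources used here do not pair with symbols, so genes are described as groups, with 4 identifiers given in full.

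The first principal component of log2 CPM (read counts scaled to a common library size) carried 21.7% of the variance and separated the injected females from most saline-injected ones. Its mean score was 32.4 in F_LPS, -8.09 in M_SAL and -25.1 in M_LPS. The F_LPS score was higher than that of M_SAL (difference 40.5, exact permutation test, adjusted p = 0.0397) and than that of M_LPS (difference 57.6, permutation test, adjusted p = 0.00054). M_LPS and M_SAL did not differ by this test (difference -17.0, exact permutation test, adjusted p = 0.328). M_SAL replicates 1 and 3 scored 44.8 and 48.0, inside the F_LPS range of -4.11 to 68.1, while the other M_SAL libraries scored between -47.8 and -7.24.

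**Figure D1:**
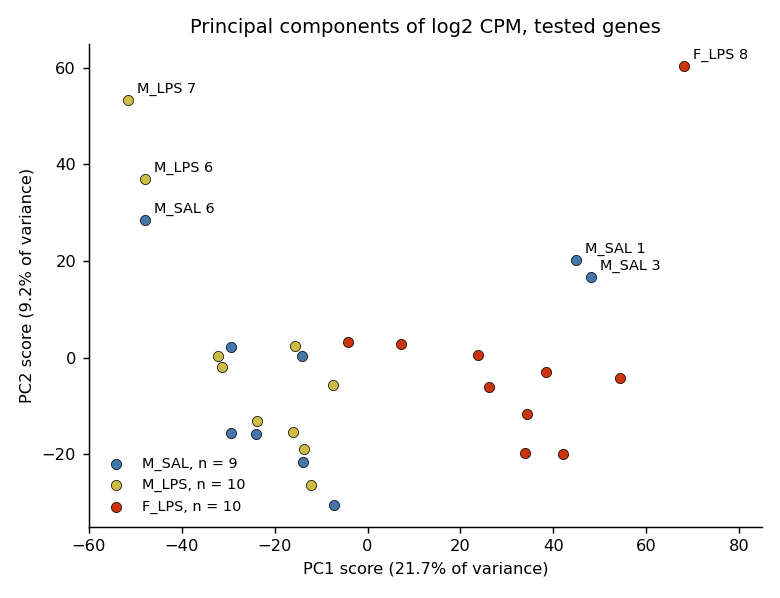
Scores of the 29 libraries on the first 2 principal components of log2 CPM of the tested genes, 1 point per library, coloured by group, with the share of variance on each axis label. Most F_LPS libraries lie to the right on PC1, M_SAL replicates 1 and 3 lie among them, and M_SAL replicate 6 with M_LPS replicates 6 and 7 lies at the far left with PC2 scores of 28.6, 37.1 and 53.4.

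LPS injection of the female was addressed by F_LPS against M_SAL, in which both groups met saline-injected males. In injected females 169 genes were higher and 60 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of the higher genes 97 rose over 2-fold and 18 over 8-fold, with a median log2 fold change of 1.13 over all 169. Of the lower genes 29 fell over 2-fold and 21 over 8-fold, with a median log2 fold change of -0.99 over all 60. The 169 higher genes together took 2.70% to 8.25% of the reads of each F_LPS library, 1.48% to 1.70% in M_LPS, and 1.42% to 1.86% in 7 of the 9 M_SAL libraries. M_SAL replicates 1 and 3 stood apart from these 7, at 3.14% and 3.69%.

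ENSCJPG00005012970 had the largest rise among the genes with a mean of at least 5 CPM in the higher group. Its level was 72.7 CPM ± 67.5 (SD, n = 10) in F_LPS against 1.57 CPM ± 2.48 (SD, n = 9) in M_SAL and 0.404 CPM ± 0.266 (SD, n = 10) in M_LPS. The log2 fold change over M_SAL was 5.52 (SE 0.73, edgeR adjusted p = 7.9e-05), and all 10 F_LPS libraries lay above every M_SAL library. ENSCJPG00005006696 followed, at 25.6 CPM ± 19.1 (SD, n = 10) in F_LPS against 0.863 CPM ± 1.58 (SD, n = 9) in M_SAL, a log2 fold change of 4.86 (SE 0.73, edgeR adjusted p = 2.2e-04), with 9 of the 10 F_LPS libraries above every M_SAL library. In both genes M_SAL replicate 3 was the highest M_SAL library, at 6.85 and 4.84 CPM, and without it the log2 fold changes were 6.35 and 6.13. They were 7.55 and 7.08 without M_SAL replicates 1 and 3, and 7.20 and 6.38 with limma voom.

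ENSCJPG00005007826 had the largest fall among the genes with a mean of at least 5 CPM in the higher group. It was at 0.0593 CPM ± 0.102 (SD, n = 10) in F_LPS, with no read in 7 of the 10 libraries, and at 6.53 CPM ± 13.8 (SD, n = 9) in M_SAL. Its log2 fold change was -6.48 (SE 1.36, edgeR adjusted p = 0.0066), and it was -4.79 (edgeR adjusted p = 0.031) without M_SAL replicate 6, which held 42.6 CPM. ENSCJPG00005014024 was at 0.463 CPM ± 0.870 (SD, n = 10) in F_LPS and 30.4 CPM ± 76.5 (SD, n = 9) in M_SAL, a log2 fold change of -5.98 (SE 1.34, edgeR adjusted p = 0.011). M_SAL replicate 6 alone held 234 CPM of this gene, and without it the log2 fold change was -3.38 and no longer passed the threshold (edgeR adjusted p = 0.12). Without F_LPS replicate 1 the 2 values were -7.24 and -6.61, and the second was -6.71 without F_LPS replicate 2. With 1 surrogate variable they were -4.14 and -3.08, and the second no longer passed. The second also missed the threshold without M_SAL replicate 6 and M_LPS replicates 6 and 7. With limma voom neither passed (-3.96 and -4.83, adjusted p = 0.259 and 0.236).

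**Figure D2:**
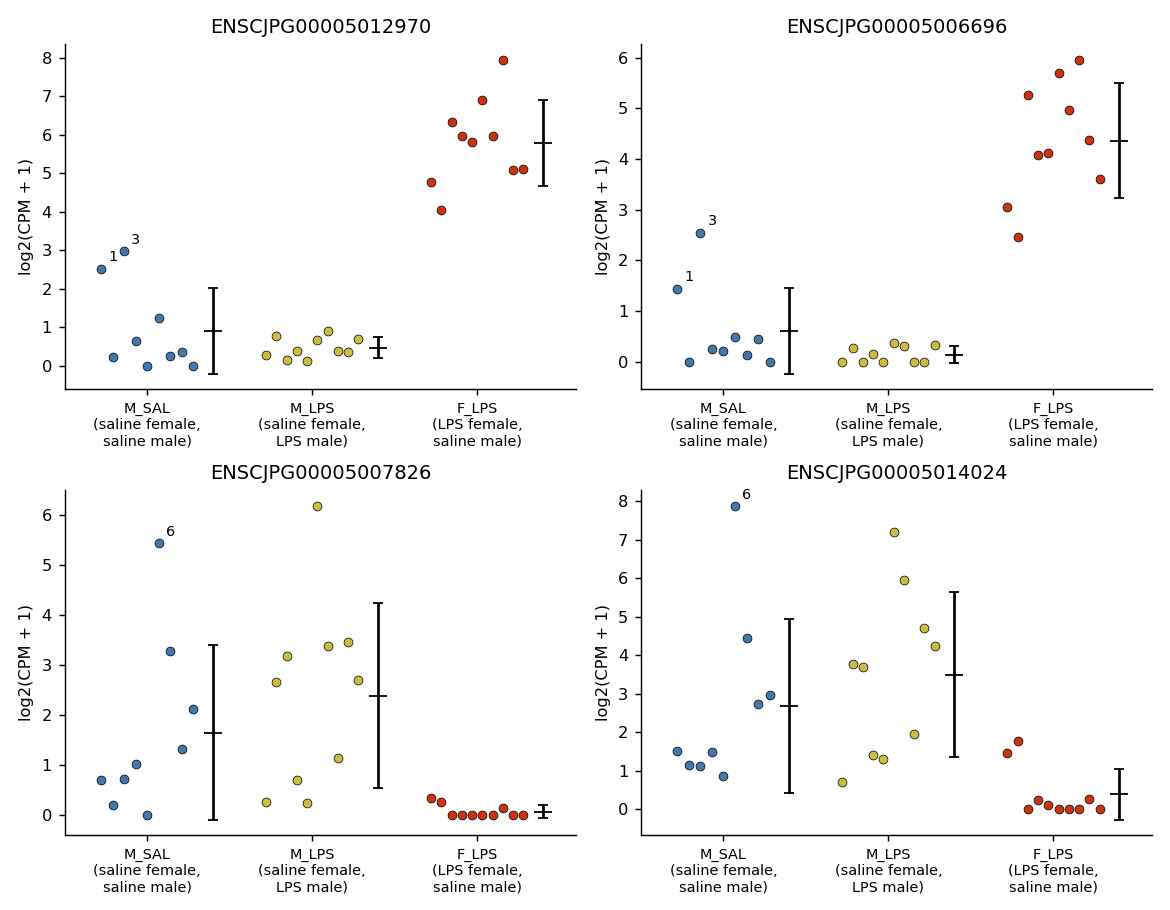
Levels of the 4 identifiers in each library, as log2(CPM + 1), by group, with the mean and SD beside the points; M_SAL replicates 1 and 3 are numbered in the upper panels and M_SAL replicate 6 in the lower panels. For ENSCJPG00005012970 all 10 F_LPS libraries lie above every other library, and for ENSCJPG00005007826 no read was counted in 7 of the 10 F_LPS libraries.

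Chance would separate every F_LPS library from every M_SAL library in 1 direction for 0.00108% of genes. Such separation was found for 10 of the higher and 5 of the lower genes. It was counted only among genes called on these same libraries, so the chance share, which is of all genes, is not a like measure. Without M_SAL replicates 1 and 3 the test called 361 higher and 94 lower genes, 455 in place of 229, and 209 of the 229 were among them. With F_LPS and M_SAL alone in the fit, 101 genes were called, 87 higher and 14 lower. DESeq2 called 350, 236 higher and 114 lower, and limma voom called 343, 281 higher and 62 lower. Without M_SAL replicate 6 the test called 134 higher and 39 lower genes, and without M_SAL replicate 6 and M_LPS replicates 6 and 7 it called 142 higher and 37 lower.

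Of the 500 most variable genes, 275 fell into 2 modules of genes that varied together across libraries. These were an upper module of 126 genes and a lower module of 149 genes, defined without reference to the groups. The upper module stood at a mean log2 CPM of 5.92 ± 1.14 (SD, n = 10) in F_LPS, 3.28 ± 1.77 (SD, n = 9) in M_SAL and 2.49 ± 0.50 (SD, n = 10) in M_LPS. It was higher in F_LPS than in M_SAL by 2.64 (exact permutation test, adjusted p = 0.0045, 6 tests), and by 3.51 (adjusted p = 1.5e-04) without M_SAL replicates 1 and 3. M_SAL replicates 1 and 3 were at 6.45 and 6.19, and the other 7 M_SAL libraries lay between 1.66 and 3.14. Of its 126 genes, 36 were called higher against M_SAL and none lower. The lower module stood at -0.33 ± 0.93 (SD, n = 10) in F_LPS, 0.91 ± 1.33 (SD, n = 9) in M_SAL and 1.57 ± 1.52 (SD, n = 10) in M_LPS. It was lower in F_LPS than in M_SAL (difference -1.24, exact permutation test, adjusted p = 0.0367), and 21 of its 149 genes were called lower. Its highest values were 3.80 in M_SAL replicate 6, 3.77 in M_LPS replicate 6 and 4.44 in M_LPS replicate 7, and without these 3 libraries the difference from M_SAL was -0.88 and missed the threshold (exact permutation test, adjusted p = 0.0813).

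**Figure D3:**
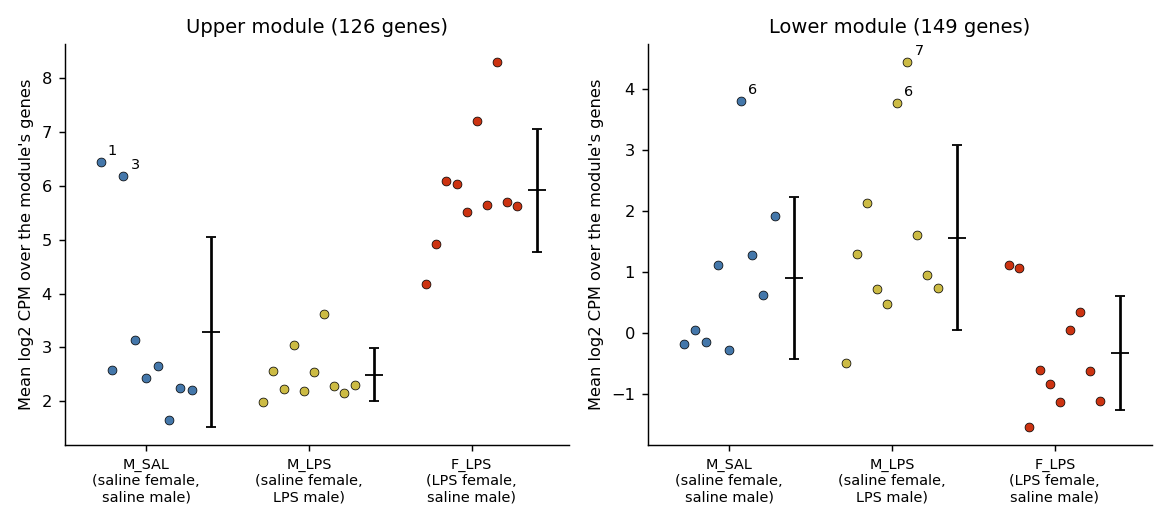
Mean log2 CPM of the upper module (126 genes) and of the lower module (149 genes) in each library, by group, with the mean and SD beside the points; numbers mark the replicates named in the text. The F_LPS libraries span 4.18 to 8.30 in the upper module, and M_SAL replicates 1 and 3, at 6.45 and 6.19, lie within that span.

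Exposure of a saline-injected female to an LPS-injected male was addressed by M_LPS against M_SAL. No gene passed an adjusted p of 0.05 with edgeR, and the smallest adjusted p was 0.427. At an unadjusted p below 0.05 there were 427 genes, 4.31% of those tested. DESeq2 called 31 genes, 1 higher and 30 lower in M_LPS, and limma voom called 0. Of these 31 genes, 24 belonged to the upper module, and DESeq2 called 0 without M_SAL replicates 1 and 3. The 4 identifiers had log2 fold changes of -1.91, -2.83, 0.78 and -0.12 in the order given above, and none passed the test (edgeR adjusted p of 0.544 or more). The first 2 were -1.08 and -1.56 without M_SAL replicate 3, and 0.12 and -0.61 without M_SAL replicates 1 and 3. The last 2 were both 2.48 without M_SAL replicate 6, and -0.55 and -1.04 without M_LPS replicate 6. The upper module differed by -0.79 (exact permutation test, adjusted p = 0.303) and the lower module by 0.66 (exact permutation test, adjusted p = 0.33). Without M_SAL replicates 1 and 3 these differences were 0.078 and 0.35. The median half-width of the 95% interval of a gene's log2 fold change was 0.45. On counts simulated with the same library sizes, the test recovered 88.2% of genes changed 4-fold, 59.9% of those changed 2-fold and 21.9% of those changed 1.5-fold in this comparison.

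The genes called in injected females were also examined in exposed females. For 223 of the 229 genes, the 95% interval of the M_LPS log2 fold change excluded the F_LPS value, and for 186 it included 0. These genes had been selected for a large change against the same M_SAL libraries. The median M_LPS log2 fold change was -0.23 over the 169 higher genes and 0.06 over the 60 lower genes. Since edgeR called 0 genes in M_LPS against M_SAL, its overlap of 0 and the expected 0 follow from that count alone. DESeq2 called 4 genes in both comparisons, where independent lists would share 1.09, and 1 of the 4 changed in the same direction. Both lists use the same M_SAL libraries, so they are not independent. DESeq2 also gave no adjusted p for 2308 of the 9918 genes in M_LPS against M_SAL. Across the 9918 genes, which are not independent replicates, the covariance of the 2 sets of log2 fold changes was -0.0261 (Pearson r = -0.167, Spearman rho = 0.066). Unchanged groups simulated against the same M_SAL libraries gave a covariance of 0.0654 on average, and the observed value minus the simulated one was -0.0915. With the M_SAL libraries split between the comparisons the covariance was -0.0789, and a permutation test over 100 regroupings gave p = 0.05, which is not below the threshold. Without M_SAL replicates 1 and 3 the covariance was 0.0318 (r = 0.170) against 0.0606 in simulation, a difference of -0.0288. It lay inside the range of the middle 95% of simulated values, 0.0112 to 0.184, while the value with all libraries lay below its range of 0.0139 to 0.167, so the departure was not seen without these 2 libraries. With the remaining M_SAL libraries split the covariance was -0.0338 (-0.106 to 0.0142, permutation p = 0.27).

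**Figure D4:**
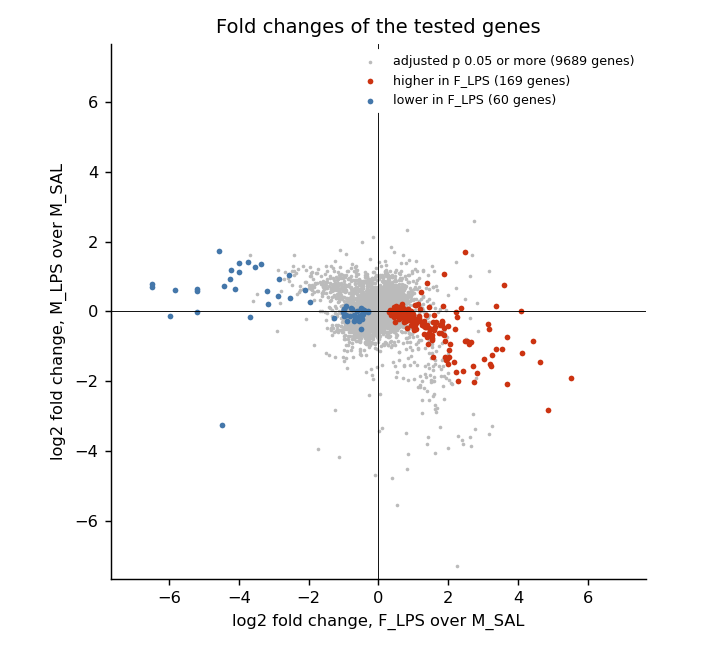
Log2 fold change of each of the 9918 tested genes in F_LPS over M_SAL (horizontal) and in M_LPS over M_SAL (vertical), 1 point per gene; red and blue mark the 169 higher and 60 lower genes of the first comparison. Both axes share the M_SAL libraries, and no gene passed the test on the vertical axis.

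The third comparison set F_LPS against M_LPS, in which both the female's injection and the male's treatment differed. In F_LPS 436 genes were higher and 227 lower (edgeR adjusted p below 0.05), 663 in all, with median log2 fold changes of 1.35 and -1.82. Over 8-fold, 105 genes rose and 46 fell. The lower count was 136 without M_LPS replicate 6 (380 higher), 140 without M_LPS replicate 7 (397 higher) and 95 without M_SAL replicate 6 and M_LPS replicates 6 and 7 (359 higher). The 4 identifiers changed in the same direction as against M_SAL. ENSCJPG00005012970 had a log2 fold change of 7.43 (edgeR adjusted p = 9.9e-07), ENSCJPG00005006696 of 7.69 (edgeR adjusted p = 1.1e-06), ENSCJPG00005007826 of -7.26 (edgeR adjusted p = 7.2e-04) and ENSCJPG00005014024 of -5.86 (edgeR adjusted p = 0.0047), the last of which missed the threshold with limma voom (adjusted p = 0.087). Without M_LPS replicate 6 the values of the 2 lower genes were -5.96 and -4.96, and without F_LPS replicate 1 they were -8.02 and -6.48. The second was -6.58 without F_LPS replicate 2, and the first was -5.24 with limma voom. With 1 surrogate variable the 4 values were 6.32, 6.31, -4.68 and -3.32. The upper module was higher by 3.43 (permutation test, adjusted p = 1.8e-04), with 120 of its 126 genes called higher. The lower module differed by -1.89 (permutation test, adjusted p = 0.0045), or -1.26 without M_SAL replicate 6 and M_LPS replicates 6 and 7, with 76 of its 149 genes called lower. The groups did not overlap for 121 of the higher and 6 of the lower genes, counted only among the called genes. Chance gives 0.000541% per direction of all genes, which is not a like measure for genes already selected.

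Of the 169 genes higher against M_SAL, 159 were also higher against M_LPS, and of the 60 lower genes 52 were also lower. Independent lists would share 7.43 and 1.37 genes. No gene changed in opposite directions. Both comparisons use the same F_LPS libraries, which can add shared calls. Unchanged groups simulated in that design had almost no calls, so they give no overlap to set beside these counts. With the F_LPS libraries split at random into 5 and 5, 1 part for each comparison, a mean over 50 splits of 107 higher genes against M_SAL and 314 against M_LPS shared 73.6 (15 to 122). Independent lists would share 2.71. Of the lower genes, 16.7 and 86.4 on average shared 6.64 (0 to 13), where independent lists would share 0.108. The split between higher and lower genes moved with the scaling, from 65.8% higher to 52.6% (371 higher, 334 lower) with upper-quartile scaling. With no filter on low counts, 482 genes were higher and 481 lower. With 1 surrogate variable in the fit, 190 genes were called.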

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

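The tests of a wrong label by separating genes, of library totals, of a swap with F_LPS libraries and of the 3 highest libraries alone were chosen after their results had been seen, and the other tests in this part before. Over 39 sets of library values, 2 held a library far from its group, where chance alone gives 1.95. M_LPS replicate 7 had 14192 genes detected against 13004 in the next library of its group, a gap of 0.567 of the group's range. F_LPS replicate 8 scored 60.4 on the second principal component against 3.31 in the next library of its group, a gap of 0.711 of the range.

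The upper module stood at 6.45 and 6.19 in M_SAL replicates 1 and 3, within the F_LPS span of 4.18 to 8.30 and above the other M_SAL libraries; library size is argued against, since the totals of both (2 of 2) lay inside the range of the other 7 M_SAL libraries. A swap with F_LPS libraries remains open: with the M_LPS mean set to 0 and the F_LPS mean to 1, on genes higher in F_LPS that were chosen without the library judged, F_LPS replicate 1 was at 0.335 (0.40 on the 436 genes chosen with it) and replicate 2 at 0.575 or more, above the 17 other saline-injected libraries (-0.118 to 0.221), but replicate 1 by less than the range of these. A wrong label without a swap partner remains open, since on 121 genes that separated F_LPS from M_LPS they lay in the F_LPS range for 92.6% and 84.3% (other M_SAL libraries 0.826% to 4.96%, the lowest held-out F_LPS libraries 16.8% in replicate 1, which lay in the M_LPS range for 30.1%, and 83.7%), and they stood together outside all F_LPS libraries at 748 genes (836 for the highest pair of F_LPS libraries, 928 for F_LPS replicate 8 with M_SAL replicate 3, the highest of 66 pairs, and a median of 231). Other values are mixed. On genes chosen with these libraries counted as M_SAL, the 60 lower genes took 0.307% and 0.371% of their reads. F_LPS libraries held 0.163% to 0.257%, and the other M_SAL libraries 0.320% to 0.433%. ENSCJPG00005012970 was at 4.73 and 6.85 CPM, below the lowest F_LPS library at 15.5. ENSCJPG00005006696 was at 1.72 and 4.84 CPM, where the lowest F_LPS library was at 4.53. On the genes lower in F_LPS than in M_LPS, M_SAL replicates 1 and 3 were at positions 0.631 and 0.691. There F_LPS libraries ran from 0.636 to 1.28, and the other saline-injected libraries reached at most 0.566. Cells of another type in a fixed make-up remain open (SD of the log2 ratio of the excess to F_LPS 1.46, at most 2.34 between F_LPS libraries), cells of any make-up cannot be told apart because 0 identifiers could be matched to markers, and an immune response to something other than the injection was not tested.

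The lower module was lowest in F_LPS and highest in M_SAL replicate 6 and M_LPS replicates 6 and 7, at 3.80, 3.77 and 4.44. Library size is argued against, because the difference between F_LPS and M_LPS was -1.83 after thinning all libraries to 1 depth, beyond the SD of 1.49 among M_LPS libraries. The 3 libraries are argued against as the whole of the difference from M_LPS, which shrank from -1.89 to -1.26 but stayed past the threshold without them (exact permutation test, adjusted p = 0.0188), but the difference from M_SAL did not (-0.88, exact permutation test, adjusted p = 0.0813). A share of cells of another type that differs between birds cannot be told apart from a change within red cells, since 0 identifiers could be matched to markers, and the injection itself remains a possible explanation.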

How the results depend on the processing

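The alternatives that leave out M_SAL replicates 1 and 3 together, or M_SAL replicate 6 with M_LPS replicates 6 and 7, the split of the F_LPS libraries and the module comparisons were chosen after seeing the data; all other alternatives were planned. The count for F_LPS against M_SAL was 229 and ran from 179 to 343 over the alternatives that kept it within 1.5 times. It was 350 with DESeq2, 101 with those groups alone in the fit and 455 without M_SAL replicates 1 and 3, and ran from 169 (without F_LPS replicate 6) to 300 (without M_SAL replicate 1) with each library left out. The cause was not tested. F_LPS against M_LPS gave 663, 454 to 963 under the other alternatives, 516 to 702 with each library left out, and 190 with 1 surrogate variable, which correlated with the first principal component with an absolute r of 0.881. M_LPS against M_SAL gave 0 except for 31 with DESeq2, of which 0 remained without M_SAL replicates 1 and 3. It gave 0 to 1 with each library left out (1 without M_SAL replicate 4), for which the cause was not tested. The overlap of calls was 0 except for 4 with DESeq2, which are among those 31.

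The covariance of fold changes was -0.0261 and its correlation -0.167, or -0.0258 and -0.166 with upper-quartile scaling. Only the covariance with the M_SAL libraries split was tested by permutation. That split value was -0.0789 (permutation p = 0.05), and -0.0785 (permutation p = 0.04) with upper-quartile scaling. Without M_SAL replicates 1 and 3 the unsplit covariance and correlation were 0.0318 and 0.170. Simulated unchanged groups gave 0.0606 there (middle 95% 0.0112 to 0.184), so the departure from the simulated range was lost. Spearman's rho was 0.066 with all libraries. With no low-count filter the covariance and correlation were -0.0140 and -0.105, and the split covariance was -0.0612 (permutation p = 0.06). With the stricter filter they were -0.0263 and -0.218, and the split covariance was -0.0640 (permutation p = 0.11). The cause was not tested. Of values that had not passed the test, ENSCJPG00005012970 in M_LPS against M_SAL moved from -1.91 to -0.021 with limma voom and -1.08 with 1 surrogate variable. It turned to 0.12, and the upper module to 0.078, without M_SAL replicates 1 and 3. ENSCJPG00005006696 moved from -2.83 to -0.61 without them, -1.56 without M_SAL replicate 3, -1.21 with limma voom and -1.70 with 1 surrogate variable, and ENSCJPG00005007826 ran from -0.55 (without M_LPS replicate 6) to 2.48 with each library left out. ENSCJPG00005014024 turned to 0.67 with limma voom, 0.24 with 1 surrogate variable and 0.90 without M_SAL replicate 6 and M_LPS replicates 6 and 7, and ran from -1.04 to 2.48 with each library left out. In F_LPS against M_SAL the 4 identifiers ran from 5.08 to 6.35, 4.62 to 6.13, -7.24 to -4.79 and -6.71 to -3.38 with each library left out. Without M_SAL replicates 1 and 3 the first 2 were 7.55 and 7.08, and the upper module difference was 3.51 in place of 2.64. The last of the 4 lost its call with limma voom (-4.83, adjusted p = 0.236), with 1 surrogate variable (-3.08, adjusted p = 0.056) and without those 3 libraries (-3.37, adjusted p = 0.059).

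The gene list tests, marker levels and cell mix covariates could not be run without symbols and are not run here, and ENSCJPG00005007826 gave no value under the stricter filter, nor with only the compared groups in the fit in F_LPS against M_SAL and F_LPS against M_LPS. ENSCJPG00005012970 and ENSCJPG00005006696 gave none with only the compared groups in M_LPS against M_SAL. No paired analysis was possible because the labels give no replicate numbers. At this depth a 1.5-fold change was recovered in 21.9% of simulated genes in M_LPS against M_SAL.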

Other observations

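The tests of how large the exposure effect is, of the left-out M_SAL libraries, of other groupings, of the relation between modules and of the 3 libraries that deviate together were chosen after the result had been seen; only the test of the DESeq2 calls was written before. On the scale where the M_LPS mean of the 436 genes higher in F_LPS than in M_LPS is 0 and the F_LPS mean is 1, F_LPS libraries ran from 0.40 in replicate 1 to 1.77 in replicate 8, and M_SAL replicates 1 and 3 stood at 0.915. In F_LPS against M_SAL the called genes made up 0.28% of the genes with a mean under 1 CPM and 1.36% of those with 1 to 10 CPM. They made up 2.28% of those with 10 to 100 CPM and 4.83% of those with 100 to 1000 CPM. Above that they made up 0.99%, which was 1 gene of 101. These differences were not tested. After thinning to 1 depth, F_LPS libraries held 12153 genes on average against 12702 in M_LPS (permutation test, adjusted p = 0.0397). M_LPS replicate 7 held 13893 genes after thinning, against 13004 in the next M_LPS library, and the test was not repeated without it. The thinned difference of F_LPS from M_SAL was -326 (exact permutation test, adjusted p = 0.171). The unthinned difference of F_LPS from M_LPS was -463 (permutation test, adjusted p = 0.0726), and neither passed.

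No gene was called in M_LPS against M_SAL. Whether precision was too little to see changes of the size found in injected females is not decided here. Genes were chosen in 5 F_LPS and 5 M_SAL libraries over 50 splits. For 82.7% of them the M_LPS interval ended before the F_LPS value of the other libraries (66.6% to 100% in the 44 splits with at least 5 genes). Simulated equal changes gave 1.53%, and simulated changes in F_LPS alone gave 94.6%. The M_LPS and F_LPS values were both taken against the same held-out M_SAL libraries. The check therefore asks mainly whether the M_LPS value fell short of the F_LPS value. In the split with most genes, 433, the medians in the direction of the change were 0.22 for F_LPS, -0.82 for M_LPS and 0.69 for the half-width. An interval centred on 0 would have included that F_LPS value. Over the 131 genes of another split they were 1.13, -1.52 and 0.90, so there it would not. The F_LPS median exceeded the half-width in every split with 141 or fewer genes, which were most of the splits. It fell short of the half-width in every split with 227 or more. The 97.4% of the 229 genes whose interval excluded the F_LPS value do not decide this either, since they were selected against the same libraries. Without M_SAL replicates 1 and 3, 0 genes were called. Leaving them out also made the M_SAL group smaller, so this count does not decide whether their spread hid changes. The same step raised the count for F_LPS against M_SAL from 229 to 455. Smaller changes and changes of other genes also remain open, since 59.9% of 2-fold and 21.9% of 1.5-fold changes were recovered in simulation. The 427 genes at an unadjusted p below 0.05 were matched or exceeded in 64 of 100 splits of the libraries, with 1289 genes in the highest other split, so chance cannot be excluded there. The other splits ranged from 165 genes to that highest count, and the source of this spread was not tested. For the 229 genes of F_LPS against M_SAL, 1 of 100 splits, the real one, gave as many, with 179 in the highest other split and 5 in the next. For the 663 genes of F_LPS against M_LPS, 1 of 100 did, with 169 in the highest other split and 20 in the next. The split with 169 left 16 of the 20 libraries in their real groups. By the number of called genes, chance is argued against for both. At an unadjusted p below 0.05, other splits of F_LPS and M_SAL gave 1525, 1391, 1314 and 1278 genes, more than the real 1161. Chance is therefore not excluded by that measure in F_LPS against M_SAL. In F_LPS against M_LPS only the highest other split, with 1819 genes, exceeded the real 1771, and the next gave 1713.

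The 31 genes that DESeq2 called in M_LPS against M_SAL may rest on M_SAL replicates 1 and 3, since 0 were called without these 2 libraries, which were the highest M_SAL libraries for 25 of the 31.

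A hypothesis that libraries with a higher upper module have a lower lower module was tested within each of the 3 groups. In M_SAL the relation was r = -0.435 (rho = -0.417, exact permutation p = 0.224, adjusted p = 0.337), and it rested on replicates 1 and 3, without which r was 0.069. In M_LPS it was r = 0.663 (rho = 0.527, permutation p = 0.035, adjusted p = 0.105), against the hypothesis, and 0.732 without replicates 4 and 7. In F_LPS it was r = -0.332 (rho = -0.455, permutation p = 0.356, adjusted p = 0.356) and -0.858 without replicates 6 and 8. No relation passed the adjusted threshold, so the data decide neither way.

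A further hypothesis is that M_SAL replicates 1 and 3 and F_LPS replicate 8 share a state beyond the injection. The set was picked from the same data, after pairs of these libraries were seen to deviate together. They were the highest of all 29 libraries at 154 tested genes, of which 16 belonged to the upper module. Among all 3654 sets of 3 libraries the mean was 2.71 genes, but 2 other sets had more, with 320 genes for M_SAL replicate 6 with M_LPS replicates 6 and 7 and 170 for M_SAL replicate 8 with M_LPS replicate 7 and F_LPS replicate 9. Such counts therefore arise for sets that cross the groups in other ways, and the test does not single this one out.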
